A study of Mus musculus with 2 samples.

How the data were processed

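Gene expression was measured in 2 samples of dendritic cells (DCs) sorted by flow cytometry from the spleens of wild-type C57BL/6 mice aged 8 weeks. DCs are the white blood cells that take up antigen and present it to T cells. Per the labels, the cells were cultured with vehicle in 1 sample and with IL-27 in the other, and total RNA was the starting material. Material prepared from it was fragmented, labelled with biotin with Affymetrix's WT Terminal Labeling Kit and hybridised to 1 array per sample. IL-27 is a cytokine of the IL-12 family. There were no replicate arrays, so every difference below lacks a replicate check, and no p-value, SD or standard error is given. The treatment label gives the duration as "ON", which was not expanded here. The labels do not say how many mice or cultures each sample came from.

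The deposited table held 1 intensity per probe set and array, on a linear scale, for 28815 probe sets. The steps from scanner image to these intensities (background correction, summarization and normalization between arrays) are not given in the sources used here. Per the submitters' processing notes, the genome build was mm8, and no coordinates are printed because the annotation used here is of another build. The values were all above 0, so log2 was taken with no pseudocount. The arrays did not share a common distribution. The median intensity was 92.4 on the vehicle array and 98.9 on the IL-27 array, the 75th percentile 267 and 215, and the range 23.7 to 14270 and 23.9 to 13202. No detection call came with the values, and the number of arrays limits the precision of every value.

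Probe sets were named from GEO's platform annotation, of which 21780 had 1 gene, 1605 had several genes and are not named, and the other 5430 are unnamed here. Of the single-gene probe sets, 21689 matched a gene ID in a RefSeq table (assembly GRCm38.p6), which changed none of the symbols. A gene with several probe sets (998 of 19935 genes) was represented by its probe set with the highest mean level. Probe sets can cross-hybridise between near-identical genes, so members of the Clec4a, Oas, Gbp and Ifit families are uncertain individually.

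The choices in this paragraph were made before the data were examined, except that random lists were drawn with replacement. A gene was counted as higher or lower by a rule of size: a log2 difference (IL-27 minus vehicle) of at least 1, that is 2-fold, with the brighter array at or above the median of all probe set values (intensity 96.2). The other genes at that level are called neither. In all, 28 gene lists were fixed: interferon-stimulated genes, JAK-STAT feedback and STAT3-linked genes, the IL-27 receptor and IL-12 family, ectonucleotidases and purine receptors, tolerance and inhibitory molecules, costimulation and maturation, MHC class I and class II presentation, inflammatory cytokines, chemokines, chemokine and adhesion receptors, pattern recognition, markers of 4 DC classes and of 6 groups of other cells, cell cycle, stress and cell death, glycolysis and hypoxia, cholesterol synthesis and efflux, ribosomal proteins, and reference genes. For each list the median difference of its measured members was set against 10000 random lists of the same size, drawn with replacement within 20 bins of mean level. A list was said to stand apart at or above percentile 99 or at or below percentile 1. The percentile describes these 2 arrays and is no p-value, since genes are not replicates. Each gene was also set against the 1000 genes nearest in mean level, by the share of them with an absolute difference at least as large. Named genes were the 15 with the largest difference in each direction among those past the size rule (clone names, predicted genes, receptor multigene families and small RNAs left out), up to 4 members per list with the largest absolute difference over the level minimum, and 22 genes named whatever their values, of which 1 is not reported here. Further members are named below as examples and were chosen after their values were seen.

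The procedure was tested on simulated data in which the differences of the 19935 genes were shuffled within level bins. All 4 lists of 20 genes shifted by 1 on the log2 scale, and all 4 shifted by 0.5, passed percentile 99 or 1 in the simulated direction. Of 2 lists shifted by 0.25, 1 did, so a list median displaced by that much can be missed. Of 100 lists with no shift, 3 did. Shuffling removed any joint variation of genes, so these rates do not carry over to lists whose genes vary together.

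Alternatives were quantile normalization, median centring, removal of the level-dependent trend by lowess (span 0.3), an offset of 16, other level filters, a 1.5-fold size rule, the mean of a gene's probe sets, and the mean of a list. After seeing the data, olfactory receptor genes were taken as a measure of the intensity of genes not expected in DCs. Where the dimmer array lay at or below their 95th percentile there, the fold was taken against that percentile and is written "at least", for genes past the size rule. The counts were also taken that way, the counts were repeated without olfactory and vomeronasal receptor genes, and 4 more lists were made, of further interferon-stimulated genes, amino acid and ATF4 response genes, NRF2 and metal response genes, and genes of CCR7-positive mature DCs. No batch label was given, and array and treatment coincide. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.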

Results

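Transcript levels were compared between splenic DCs cultured with IL-27 and with vehicle, which addresses how the cytokine changes gene expression in these cells. Each condition was read on 1 array, and all differences are between these 2 arrays. Log2 intensities of the 28815 probe sets correlated with r = 0.936 across probe sets, which are not independent replicates. The 1027 olfactory receptor genes, not expected in DCs, had a median intensity of 40.5 on the vehicle array and 59.0 on the IL-27 array. Their 95th percentiles, 77.3 and 129, were taken, after the data were seen, as the olfactory limit below which a gene could not be told from genes not expected here. For genes past the size rule whose dimmer array lay at or below its limit, the fold was taken against the limit and is given as "at least".

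Markers of macrophages and conventional DCs, interferon-stimulated genes, cell cycle genes and pattern recognition genes were lower on the IL-27 array, with list medians from -0.92 to -1.56 on the log2 scale. Costimulation and maturation genes were higher as a list, with a median of 0.32, though none of 16 over the level minimum was higher by the size rule. Among single genes, Emp1 and Tnip3 were 7.94-fold and 6.96-fold higher, and Gfra2 and Ccr3 7.86-fold and 6.72-fold lower. Of the 28 gene lists, 3 lay at or above percentile 99 of level-matched lists and 8 at or below percentile 1. Genes of a list can vary together and some lists share members, so no chance level is set beside these counts. Olfactory receptor genes themselves lay at percentile 100 of level-matched lists, so a percentile alone does not show a difference in expression. By the rule of size, 1468 of 19935 genes were lower and 169 were higher. Of the higher genes, 144 exceeded the olfactory 95th percentile on the IL-27 array. On the dimmer array, 511 of the lower genes and 55 of the higher genes lay at or below its percentile, so the size of their deposited differences is not fixed. Against the percentile, 1131 lower and 127 higher genes still differed 2-fold. Olfactory and vomeronasal receptors made up 33 of the higher genes and 0 of the lower genes. The difference depended on level. Its median was 0.24 in the level bin around an intensity of 59.9 and -0.57 around an intensity of 263, and it returned to -0.26 in the brightest bin. Higher genes made up 10.3% of the genes past the size rule as deposited, 20.6% after quantile normalization (235 higher, 907 lower) and 26.2% after removal of the level trend (264 higher, 744 lower). With the trend removed, Tyk2, H2-DMa, H2-Oa, Ctss, Psmb10, Erap1, Clec4e, Nfkbiz, Cxcl2, Cxcl13, Entpd6, Dpp4, Ms4a1, Klrk1, Klrd1, Atf3, Pfkl and Hprt were short of a 2-fold difference, and Cd80, Cflar, Tnfsf9, Tnf and Pfkp were past it. Single differences below and their calls are as deposited, and each gene list is set against lists matched on level.

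**Figure D1:**
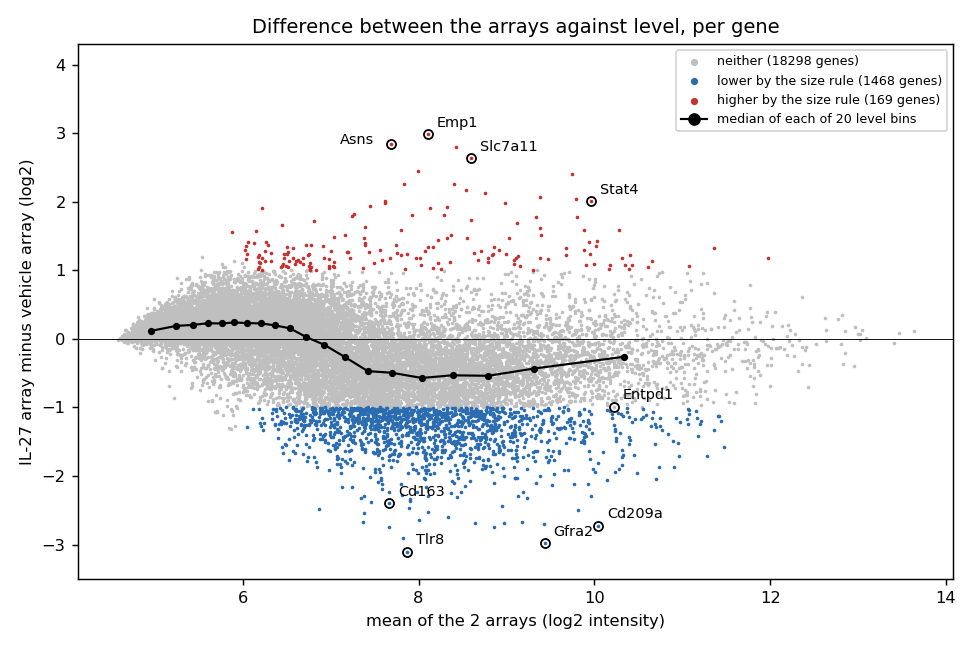
Difference between the arrays (IL-27 minus vehicle, log2) against the mean log2 intensity of both arrays, 1 point per gene, with the 169 higher genes in red, the 1468 lower genes in blue and the median of each of 20 level bins as a black line. The line lies above 0 for dim genes and reaches its lowest value, -0.57, at intermediate levels.

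Among the 15 genes with the largest positive differences, Emp1 (probe set 10542355), an epithelial membrane protein, was 7.94-fold higher, at an intensity of 97.9 with vehicle and 777 with IL-27. Asns, asparagine synthetase, was at least 7.12-fold higher, from a vehicle value of 76.6. Slc7a11, the cystine transporter, was 6.23-fold higher and Chac1, a glutathione-degrading enzyme, 4.48-fold. Mt2, a metallothionein, was 5.28-fold and Srxn1, sulfiredoxin, 4.77-fold higher. Tnip3, which binds the NF-kB inhibitor A20, was 6.96-fold higher. Stat4, the transcription factor downstream of IL-12, had an intensity of 496 with vehicle and 1994 with IL-27, which is 4.02-fold higher. The integrin subunit Itga5 was 4.36-fold higher, Ndrg1 4.17-fold, the receptor partner Ramp3 5.45-fold and the zinc finger repressor Zbtb32 3.94-fold. Mpp7 was 4.80-fold higher by its brighter probe set, and its probe sets ranged from 1.09 to 2.26 on the log2 scale. Niban2 and Tm4sf19 were 4.04-fold and 3.81-fold higher.

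Among the 15 genes with the largest negative differences as deposited, Tlr8, an endosomal RNA sensor (probe set 10607868), was at least 5.30-fold lower on the IL-27 array, at an intensity of 686 with vehicle and 79.8 with IL-27. Gfra2, a receptor for neurturin, was 7.86-fold lower, from 1940 to 247. The C-type lectins Cd209a and Clec4a3 were 6.61-fold and 6.47-fold lower, and Clec1b at least 4.07-fold. The chemokine receptor Ccr3 was 6.72-fold lower, and the atypical receptor Ccrl2 6.42-fold. The potassium channel genes Kcnj10 and Kcnj16 were 6.40-fold and at least 4.77-fold lower. Tlr3, the double-stranded RNA sensor, was at least 4.98-fold lower, Slc14a1 at least 5.12-fold, Sesn1 at least 3.23-fold and Slc16a7 at least 3.09-fold. Bex6 and P2ry13 were 6.08-fold and 5.67-fold lower. Genes whose fold is a bound have no fixed rank among these 15.

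**Figure D2:**
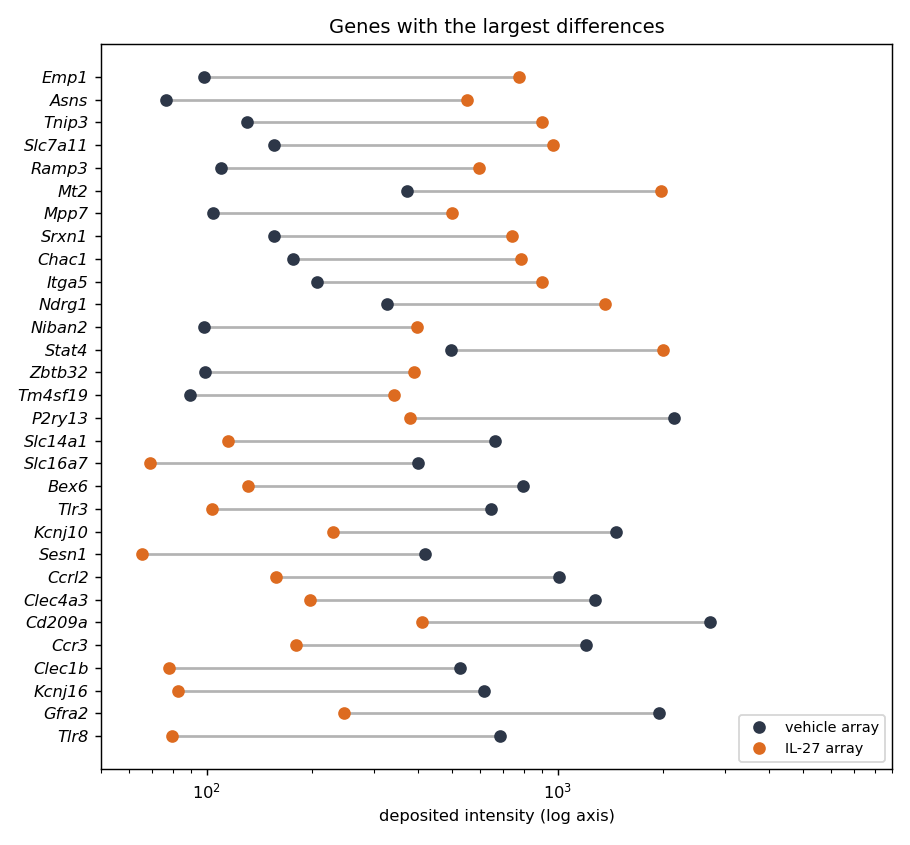
Deposited intensity (log axis) on the vehicle array (dark points) and the IL-27 array (orange points) for the 15 genes with the largest positive and the 15 with the largest negative difference as deposited, each joined by a line. Emp1 went from 97.9 to 777 between the arrays and Tlr8 from 686 to 79.8.

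The IL-27 receptor chains and the feedback genes Socs1, Socs3 and Irf1 did not pass the size rule, whereas Stat4 was higher and Tyk2, a kinase of the receptor complex, lower. Il27ra, the ligand-binding receptor chain, had an intensity of 152 with vehicle and 125, below the olfactory limit, with IL-27, and Il6st, its signalling partner, 1414 and 1205. Socs3 (224 and 216), Socs1 (170 and 175) and Irf1 (858 and 941), which are induced through STAT factors in many cells, differed by at most 1.10-fold as deposited by their brighter probe sets (another of Socs3 by 0.22), and Stat3 had 1192 and 1596. Other culture times were not measured, so a change at another time would not be seen. The difference of Il6st turned from -0.23 to 0.01 with the level trend removed, and that of Socs3 from -0.05 to 0.33. Socs1 went from 0.04 to -0.06 with median centring. The IL-12 family and receptor list had a median difference of -0.21 (percentile 54.0), which turned to 0.02 with the level trend removed. Of its 11 members over the level minimum, Stat4 was higher, Tyk2 was 2.16-fold lower (-0.68 in place of -1.11 with the level trend removed) and 9 were neither. Ebi3, a subunit of IL-27 itself, had 465 with vehicle and 250 with IL-27, and Il12rb1 111 and 173. Il27 had 164 and 200, Il12b had 877 and 720 (0.04 in place of -0.29 with the level trend removed), and Il12a lay within the olfactory range on both arrays. The JAK-STAT feedback list had a median of -0.11 (percentile 93.8), or 0.03 with the level trend removed, -0.22 with only members over the level minimum and -0.21 by the mean, and none of its 23 members over the level minimum passed the size rule. Its largest differences were those of Zfp36, Fosl2, Bcl6 and Il10ra, at -0.93, -0.91, -0.90 and -0.86.

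Of 42 interferon-stimulated genes over the level minimum, 24 were lower, 1 was higher and 17 were neither. The list's median was -1.09, a 2.13-fold lower level, against -0.39 in level-matched lists, and it lay below all 10000 of them (percentile 0). Ddx58, which encodes the RNA sensor RIG-I, was 3.92-fold lower, Ifit3 3.64-fold, Samd9l at least 2.30-fold and Eif2ak2, the RNA-activated kinase PKR, at least 1.73-fold. Irf7 was lower by a log2 difference of -1.42 and Usp18 by -1.64. Oasl1, the higher gene, had a log2 difference of 1.47. Against the olfactory limit, 21 of the lower genes still differed 2-fold. With the level trend removed the median was -0.76. Macrophage and monocyte markers were lower alongside, with a median of -1.56.

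Ectonucleotidases, which split extracellular ATP, and purine receptors were lower as a list. Of 14 members over the level minimum, 7 were lower and 0 higher, with a median over all 22 measured members of -0.45 (percentile 0.71). With only the members over the level minimum the median was -1.004. An offset of 16 moved that percentile to 1.30, past the limit of 1. P2ry13, P2ry12 and P2rx7, receptors for ADP or ATP, were 5.67-fold, at least 2.14-fold and 2.86-fold lower, and Entpd6 2.60-fold. Entpd1 (probe set 10463070), the ectonucleotidase CD39, had an intensity of 1684 with vehicle and 849 with IL-27. This is 1.98-fold lower and just short of the size rule, and 14.7% of the 1000 genes nearest in level differed by as much. With the level trend removed its difference was -0.73 in place of -0.99. Nt5e, which makes adenosine from AMP, lay within the olfactory range on both arrays. Macrophage and monocyte markers, which share no member with this list, were lower alongside (median -1.56).

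Tolerance-related and inhibitory molecules were not displaced as a list. Their median was -0.12 (percentile 20.8), or -0.34 with only members over the level minimum and -0.22 with median centring, with 5 lower, 1 higher and 17 neither among 23 members over the level minimum. Btla, Tnfrsf14, Fgl2 and Lgals9, all with inhibitory functions in lymphocytes, were 3.23-fold, 3.08-fold, 3.05-fold and 2.86-fold lower. Il1rn, the IL-1 receptor antagonist, was the higher gene, with a log2 difference of 1.51. Il10 had an intensity of 94.6 with vehicle and 61.1, below the olfactory limit, with IL-27, Tgfb1 1635 and 1166, and Cd274, which encodes PD-L1, 1495 and 1489 (0.21 in place of -0.01 with the level trend removed). Ido1, a tryptophan-degrading enzyme, lay within the olfactory range on both arrays.

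Costimulation and maturation genes were higher as a list, although none of the 16 members over the level minimum was higher by the size rule as deposited. With the level trend removed, Cd80, Cflar and Tnfsf9 were (Cd80 at 1.10). The list's median was 0.32, against -0.23 in level-matched lists, and it lay above all of them (percentile 100). Of its 20 measured members, 15 had a difference above 0. The mean of the list was 0.20. Macrophage and monocyte markers were lower alongside (median -1.56). Cd80 had an intensity of 1731 with vehicle and 3357 with IL-27 (1.94-fold higher), though its other probe set differed by only 0.29. Cd40 was 1.40-fold and Cd86 1.19-fold higher, Cflar 1.56-fold and Tnfsf9, which encodes 4-1BB ligand, 1.54-fold. Cd48, the member past the size rule, was 2.80-fold lower, and Icosl, Cd44, Icam1 and Relb differed by -0.57, -0.35, -0.11 and -0.10.

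Antigen presentation genes as lists did not stand apart. The MHC class II list had a median of -0.50 (percentile 9.78), or -0.29 with the level trend removed, with 4 of 14 lower. Ciita, the master regulator of class II genes, was 3.18-fold lower, H2-DMa and H2-Oa were 2.23-fold and 2.04-fold lower, and the protease gene Ctss had 1872 and 934. The class II chains H2-Aa, H2-Ab1 and H2-Eb1 differed by 0.12, -0.02 and -0.08. The class I list had a median of -0.40 (percentile 38.4), or -0.05 with the level trend removed and -0.09 with quantile normalization, with 2 of 17 lower, Psmb10 by 2.17-fold and Erap1 by 2.16-fold. With the level trend removed these had -0.68 and -0.71, and H2-DMa, H2-Oa and Ctss -0.98, -0.74 and -0.76, so that of these calls only that of Ciita (-1.34) stayed. H2-M3 and Psmb8 were 1.98-fold and 1.70-fold lower, short of the size rule.

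Pattern recognition genes were lower as a list, and chemokines went both ways. Of 27 pattern recognition genes over the level minimum, 13 were lower and 1 was higher, with a list median of -0.92 (percentile 0). Beside Tlr8, Tlr3 and Cd209a, Tlr7 was 4.31-fold and the mannose receptor Mrc1 4.34-fold lower, while Tlr9 differed by -0.08 (0.22 with the level trend removed). Macrophage and monocyte markers were lower alongside these too (median -1.56). Clec4e, a lectin sensing mycobacterial glycolipid, was the higher member, at least 1.70-fold. Against the olfactory limit 11 were lower and 0 higher. Among inflammatory cytokines, whose list median was 0.05 (percentile 26.6) and turned to -0.15 with the level trend removed, 4 of 9 members over the level minimum were lower. These were Il18 (4.12-fold), Ptgs2, the prostaglandin-forming enzyme (3.66-fold), Nfkbiz (2.18-fold) and Il15 (at least 1.88-fold). Tnf had 466 and 784, and Il6 lay within the olfactory range on both arrays. With only the members over the level minimum the cytokine list had a median of -0.95 and stood apart downward (percentile 0.45). Chemokines had a median of 0.09 (percentile 98.8), or 0.01 with the level trend removed and -0.01 with median centring. Of 18 chemokines over the level minimum 4 were lower and 2 higher. Cxcl11 was 2.77-fold and Ccl22 2.13-fold higher, and Ccl6, Cxcl13, Cxcl2 and Ccl24 were 3.07-fold, 2.09-fold, 2.08-fold and at least 1.18-fold lower. Chemokine and adhesion receptors had a median of -0.48 (percentile 4.33), or -0.31 with the level trend removed, with Ccr3 and Itga6 (at least 1.35-fold) lower, and Itgal and Ccr9 1.91-fold and 1.85-fold lower without passing the size rule.

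Markers of conventional DCs and of macrophages were both lower on the IL-27 array, and those of lymphocytes did not stand apart. Of 18 macrophage and monocyte markers, 14 were lower and 0 higher, with a median of -1.56 (2.94-fold lower, percentile 0). Cd163, a haemoglobin scavenger receptor, was at least 3.59-fold lower, Slc40a1, the iron exporter of red pulp macrophages, 4.12-fold, Mertk 3.86-fold and Fcgr4 3.77-fold. Lyz2 and Hmox1 differed by -0.42 and -0.16. Of 13 type 2 DC markers over the level minimum, 8 were lower, with a median of -1.16 over 16 measured members (percentile 0). Clec4a1 was 3.28-fold, Clec4a4 at least 2.29-fold and Clec4a2 at least 1.60-fold lower, and Irf4, a transcription factor of these cells, differed by 0.40. Of 14 type 1 DC markers 7 were lower, with a median of -1.02 (percentile 0.04). Gpr141b, Cd8a and the chemokine receptor Xcr1 were 3.89-fold, 2.88-fold and 2.82-fold lower, and Clec9a differed by -0.59. Of 10 pan-DC markers 6 were lower, with a median of -1.05 (percentile 0.15). Kmo was 4.92-fold and Dpp4 2.14-fold lower, Itgax, which encodes CD11c, differed by -0.88, and Zbtb46 by -0.02 (0.42 with the level trend removed).

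Plasmacytoid DC markers had a median of -0.47 (percentile 33.4), or -0.03 with the level trend removed, with Lair1 at least 4.45-fold lower and Tcf4, the defining transcription factor of these cells, 1.77-fold lower. T cell markers had a median of 0.08 (percentile 36.8), which turned to -0.09 with the level trend removed, and Cd4, also carried by splenic DCs, was 2.82-fold lower, Cd5 differed by -0.30 (0.02 with the trend removed), and Cd3e and Lat differed by 0.48 and 0.68 at intensities no higher than 129. B cell markers had a median of -0.05 (percentile 86.9), or -0.14 with median centring, with Cd22 at least 3.05-fold and Ms4a1 2.15-fold lower, Blnk 1.70-fold lower and Ighm 2.39-fold higher by 1 of its probe sets (0.07 by another). NK cell markers had a median of 0.16 (percentile 65.1), or 0.07 with the level trend removed, with Klrk1 and Klrd1 2.12-fold and 2.06-fold lower and Il2rb and Prf1, within the olfactory range on the IL-27 array, differing by 0.51 and 0.25. Neutrophil and mast cell markers had a median of 0.30 (percentile 96.7), or 0.09 with the level trend removed. Csf3r and Mmp9 were at least 2.12-fold and at least 1.24-fold lower, Cxcr2 had 117 with vehicle and 55.4, below the olfactory limit, with IL-27, and S100a9 differed by 0.78. Erythroid and stromal markers had a median of 0.18 (percentile 79.5), or -0.05 with the level trend removed, with Pecam1 3.55-fold lower and Col1a1 differing by 0.47. Col3a1 and Kdr, within the olfactory range on the IL-27 array, differed by 0.40 and -0.39.

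**Figure D3:**
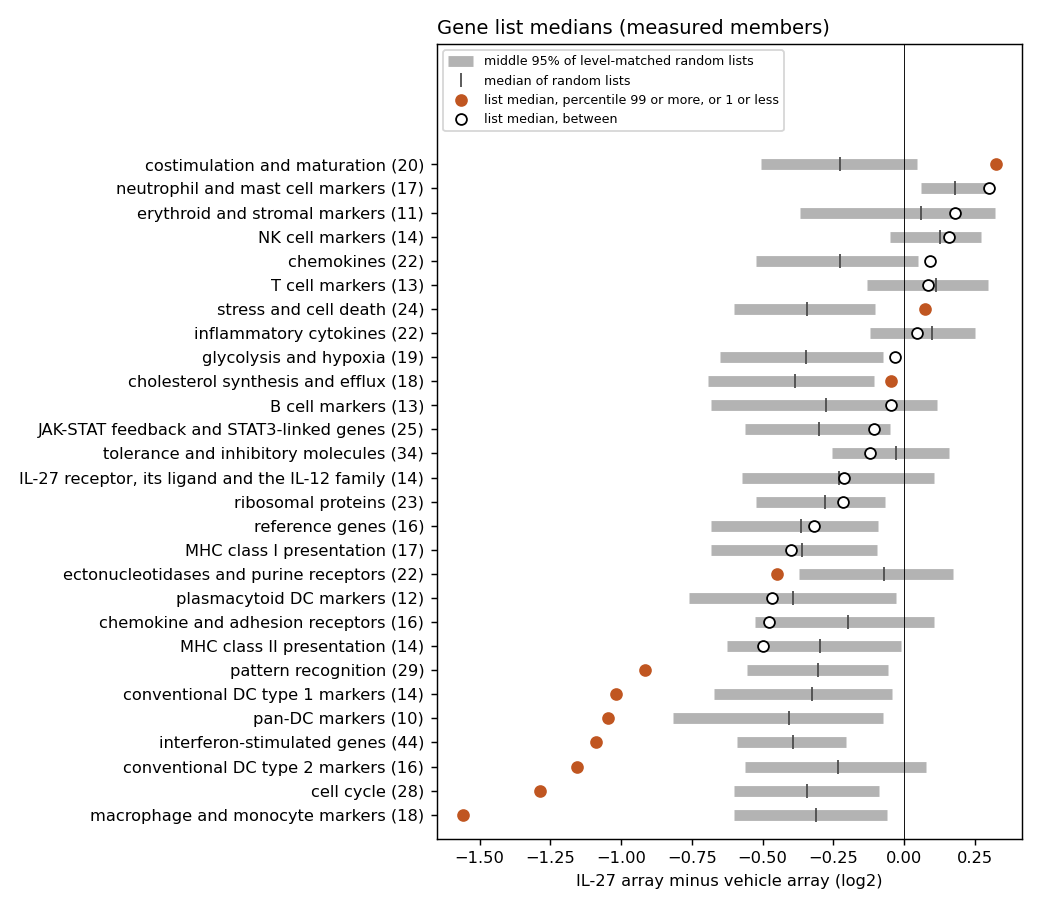
Median log2 difference (IL-27 minus vehicle) of each of 28 gene lists, with the number of measured members in brackets. Grey bars span the middle 95% of level-matched random lists, and filled points mark lists at or above percentile 99 or at or below percentile 1. Macrophage and monocyte markers lie lowest, at -1.56, and costimulation and maturation highest, at 0.32.

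Proliferation genes were lower and stress genes were split. Of 28 cell cycle genes 20 were lower and 0 higher, with a median of -1.29 (percentile 0), and macrophage and monocyte markers were lower alongside (median -1.56). Ccna2 and Bub1, which act in mitotic entry and the spindle checkpoint, were 3.77-fold and at least 2.44-fold lower, the spindle motor Kif11 at least 3.05-fold and the ribonucleotide reductase subunit Rrm2 at least 2.93-fold. Against the olfactory limit, 15 of the 20 still differed 2-fold. Of 23 stress and cell death genes over the level minimum, 6 were higher and 6 lower, and the median of 0.07 lay at percentile 99.9. The median turned to -0.025 with median centring and was 0.19 with the level trend removed. The higher members were Asns, Chac1, Bcl2l11, Hsph1, Sqstm1 and Gadd45b. The lower members were Fos (4.89-fold), Casp1 (at least 2.58-fold), Txnip, Egr1, Atf3 and Jun, which include immediate early genes.

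Cholesterol synthesis and efflux had a median of -0.05, where level-matched lists lay at -0.39 (percentile 99.01), and with the level trend removed it had 0.19 (percentile 98.5). The sterol pathway enzymes Msmo1 and Idi1 were 2.26-fold and 2.03-fold higher, Idi1 by its brighter probe set. Its other probe set differed by 0.92 on the log2 scale, short of the size rule. Apoe was 1.62-fold lower, also short of that rule. Dhcr7 had 138 with vehicle and 84.2, below the olfactory limit, with IL-27. Glycolysis and hypoxia genes had a median of -0.03 (percentile 98.5), which turned to 0.23 with the level trend removed (percentile 99.2), with Slc16a3, the lactate exporter, 2.11-fold and Pfkp 1.97-fold higher and Pfkl at least 1.82-fold lower. Ribosomal proteins had a median of -0.22 (percentile 74.2), or -0.09 with the level trend removed, with none of 23 past the size rule. Rps9, Rpl14 and Rps19 lay at -0.71 (-0.16 by the other probe set of Rps9), -0.66 and -0.43. Rpl30 had 184 with vehicle and 127, below the olfactory limit, with IL-27. Reference genes had a median of -0.32 (percentile 63.0), or -0.03 with the level trend removed. Actb and Ppia differed by -0.06 and -0.10 (Ppia by 0.02 with the level trend removed), whereas Hprt and Tfrc were 2.52-fold and at least 1.83-fold lower, and Sdha and Gusb 1.83-fold and 1.46-fold.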

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

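The tests in this part were chosen after the result was seen. Among the 5430 probe sets with no gene name, which enter none of the comparisons, 438 were higher and 107 lower on the IL-27 array by the size rule. Their median difference was 0.17. Each was also given the median of named genes in its level bin, and the median of these bin medians was 0.12. The median intensity of the unnamed probe sets was 73.3, against 98.8 for named genes. At the shares of named genes of the same level, 36.8 of the unnamed probe sets would be higher and 301 lower. They were picked out as data that enter no comparison.

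On the IL-27 array dim probe sets were higher and most bright genes lower. An added background on the IL-27 array alone would raise dim probe sets and lower none, but the lowest of the 20 level bins had a median of -0.57, so it is excluded as the whole cause. A single scaling factor would shift all levels alike, but the highest and lowest bin medians lay 0.81 apart, so it is excluded as the whole cause too. Scaling that depends on level, background and a factor together, differences in RNA or hybridization, and a broad effect of IL-27 itself stay open, since array and treatment coincide. Olfactory receptor genes were higher by 0.46 where genes of the same level were higher by 0.18 (percentile 100). Genes not expected in DCs thus stood apart upward as well, so matching on level did not remove every difference between the arrays.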

How the results depend on the processing

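All alternatives were chosen before the data were examined, except the counts without olfactory and vomeronasal receptor genes, those against the olfactory limit, and the settings of the 4 later lists. With the level trend removed, 264 genes were higher and 744 lower, of which 144 and 688 were among the 169 and 1468 counted as deposited. Quantile normalization gave 907 lower genes, the 75th percentile as level filter 101 higher genes, and a 1.5-fold rule 653 higher and 3753 lower. Without the receptor genes 136 were higher, and against the limit 127 were higher and 1131 lower. Lower genes outnumbered higher ones under each of these settings and the others run. All 95 named genes past the size rule kept their direction under the 4 other scalings and the mean of probe sets, and 81 to 93 of them stayed past it. The kept direction is little support. These genes were picked for a log2 difference of at least 1, and the level bin medians ran only from -0.57 to 0.24. Under each alternative, 25 to 28 lists stayed on their side of percentiles 99 and 1. Median centring shifts all genes alike, so it could not move a percentile. Ectonucleotidases and purine receptors moved to percentile 1.3 with the offset of 16. Inflammatory cytokines moved to 0.45 with only members over the level minimum, and chemokine and adhesion receptors to 0.27 by the mean. Glycolysis and hypoxia reached 99.17 with the trend removed and 99.94 by the mean. Cholesterol synthesis and efflux lay at 97.82 with quantile normalization, 98.47 with the trend removed, 98.99 with the offset and 95.93 with members over the level minimum. Its median was 0.11 with quantile normalization, 0.19 with the trend removed and 0.028 by the mean. The stress median was -0.025 with median centring and -0.062 with members over the level minimum. The 4 later lists were put through the same alternatives after their values were seen, and 3 stayed on their side of percentiles 99 and 1 throughout. The NRF2 and metal list, at 98.88, moved to 99.04 with the offset and to 77.73 with the trend removed. The causes were not tested. Neutrophil and mast cell markers had too few members over the level minimum for a value there. Genes below the olfactory 95th percentile on both arrays cannot be told from genes not expected in DCs.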

Other observations

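In this part, the lists of further interferon-stimulated, CCR7-positive mature DC, amino acid response and NRF2 genes were written after the data were opened but before the values of their members were seen, with Tlr9 as the exception, and the other tests were chosen after the result was seen. Amino acid response genes outside the fixed lists were shifted upward. Of 36 measured genes 32 had a difference above 0, and the median was 0.52 against -0.33 in level-matched lists. By the size rule 4 of 31 members over the level minimum were higher and 1 lower. On the stress list, Asns and Chac1 were higher and Atf3 lower as deposited, and Atf4 itself was not among the genes past the size rule. The tRNA synthetase genes Cars and Yars had differences of 1.34 and 1.12, the arginine transporter Slc7a1 1.29, and the mitochondrial folate enzyme Mthfd2 1.23. Psat1 and Phgdh, of serine synthesis, had 0.80 and 0.69, and Ddit4 was the lower member, at -1.53. That list lay at percentile 100, so Asns, Chac1 and Slc7a11 may be part of an amino acid and ATF4 response, a hypothesis from 2 arrays that does not separate IL-27 from other differences between the cultures, such as nutrient supply.

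Of 23 genes of an NRF2 and metal response, 11 had a difference above 0 and 12 below, and the median was -0.02 against -0.33 in level-matched lists. By the size rule 0 were higher and 3 lower (Blvrb, Cat and Gsta4). Gclc and Txnrd1 differed by 0.98 and 0.84, while Blvrb and Cat differed by -1.45 and -1.14. The list lay at percentile 98.9, short of 99, and at 77.7 with the level trend removed, so whether Srxn1, Slc7a11 and Mt2 may belong to such a response is left undecided.

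Interferon-stimulated genes were lower on the array labelled IL-27. The level trend does not account for it, since the list's median was -0.76 with the trend removed, nor does the choice of list members, since a second list of 36 genes lay at percentile 0 with 15 lower and 0 higher. A candidate explanation is that the 2 arrays carry exchanged labels. In that case the JAK-STAT feedback list might also be low, and it lay at percentile 93.8. None of its 23 members over the level minimum passed the size rule, and its response to IL-27 in these cells is not known. That list therefore cannot decide for or against exchanged labels. No gene identifies the samples, so exchanged labels and a lower level with IL-27 cannot be told apart. Other differences between the samples or arrays stay open too, since array and treatment coincide. Among them is the share of macrophages, whose markers were lower alongside (median -1.56).

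Macrophage and DC subset markers were lower on the array labelled IL-27, together with cell cycle and pattern recognition genes. Costimulation genes were higher as a list only, with none of 16 over the level minimum higher by the size rule. A lower share of macrophages alone would leave DC markers at or above genes of their level. The pan-DC list lay at percentile 0.15, with all 10 members below 0, which argues against it as the whole cause. That account is not excluded, since Zbtb46 hardly differed as deposited and whether the members are confined to DCs was not tested. A lower share stays open for the macrophage list itself, whose brightest genes Vcam1, Hmox1 and C1qb had differences of -1.58, -0.16 and -1.20. A sort for DCs might be expected to keep that list low, but how far it removed macrophages was not tested. On the vehicle array Slc40a1 had an intensity of 3390 and Mertk 2023, where the 75th percentile of probe sets was 267. Of the 18 genes of the list, 1 is also a type 2 DC marker. A further advanced maturation of the DCs may underlie the DC part: genes of CCR7-positive mature DCs lay at percentile 100, with a median of 0.09 against -0.38 in level-matched lists, though 1 of 38 (Basp1) was higher and 2 (Spag5 and H2-M2) lower by the size rule, 1 of them against the olfactory limit. Of the 38, 20 had a difference above 0 and 18 below, and the mean was 0.018. The median was -0.0075 with median centring, which cannot move a percentile, and 0.39 with the level trend removed (percentile 100).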
